A study of Mus musculus with 4 samples.

How the data were processed

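Total RNA from 4 cultures was biotin-labelled and hybridised to Affymetrix Mouse Genome arrays, 1 array per culture. Per the submitters' processing notes the arrays were processed with Affymetrix Power Tools, whose version is not given in the sources used here. The deposited values were taken as log2 expression values per probe set because they run from 2.48 to 15.09, a range that fits that scale; the base of the logarithm, the summarisation algorithm, the background correction and any centring are not given in the sources used here. Values on another logarithmic base would change every fold change printed. No genome build is named, so no coordinates are given. Array medians differed by up to 0.24 and were left as deposited in the main results.

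Groups were taken from the sample titles. The genotype label of both deficient samples carries the Cre transgene yet ends in the words for wild type, which conflicts with the title, and the levels of the targeted genes are given in the results as a check. Cell sorting, cytokine doses and the 72 h culture are as the labels give them.

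The array has 45101 probe sets. The platform annotation names 1 gene for 34958 of them, several for 932 and none for 9211, including 64 controls. Probe sets naming several genes or none were left out of gene results. Symbols were checked through Entrez identifiers against RefSeq genes of GRCm38.p6, used for names only: 96.8% of identifiers matched and 0 symbols changed. A gene's value is that of the probe set, among those naming it alone, with the highest mean over the 4 arrays. Genes were kept where the highest of their 4 values exceeded 6.20, the median (percentile 50) of all values, which left 12439 of 18193 (68.4%). No detection call was used, so signal over background is known only through this level.

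Comparisons made were STAT3-deficient minus STAT3 wild type, STAT5-deficient minus STAT5 wild type, and STAT5 wild type minus STAT3 wild type. With 1 array per group, the results are differences of log2 values with no test, standard error or p-value, and a gene counts as higher or lower at a difference of 1 (2-fold) or more in size. The overlap of gene sets is given beside the product of their sizes divided by the number of genes. Pearson and Spearman correlations are across genes. No overlap between the wild-type difference and another difference is given because they share an array.

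Gene lists were fixed before the data were examined: Th17, regulatory T cell, Th1, Th2, follicular helper, IL-2 and STAT5 induced or repressed, IL-6 and STAT3 induced, interferon, cell cycle, apoptosis, glycolysis, cholesterol synthesis, naive and central memory, cytotoxic, T cell receptor early response, TGF-β response, heat shock, amino acid and unfolded protein response, CD4 T cell identity, markers of B, myeloid, NK, CD8, gamma delta T and erythroid cells, sex-linked genes and neighbours of the targeted locus. Some genes stand on several lists. A list's median difference is given with its percentile among 10000 random lists, as a description of these arrays. The random lists had the same size and were matched on mean expression in 20 bins. A list stands apart under percentile 2.5 or above 97.5. Random lists hold genes that need not vary together, whereas members of a list can be regulated together. A small joint shift between single cultures can thus reach an extreme percentile, which is not a p-value. The cell cycle list without STAT3 stood apart although none of its genes passed 2-fold. Members that no probe set names alone were not analysed here, and members under the filter were left out of medians. Lists with fewer than 3 measured members have no median.

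The genes named were also set by a rule written before the data were examined. It names 12 genes always (the targeted genes and key Th17, regulatory T cell and cytokine signalling genes), 2 of which were not analysed here. It adds, for each deletion, the 10 largest increases and 10 largest decreases whose probe sets all moved the same way, and up to 4 members of each list with the largest differences past 2-fold, or the farthest member where none passed. For the wild-type difference it adds 5 increases and 5 decreases, and for genes with opposite effects the 5 with the widest gap in each direction. Other list members named were chosen after their values were seen.

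Where a gene had several probe sets past the filter, all moved the same way for 472 of 510 called genes (92.5%) in the STAT3 comparison, 139 of 153 (90.8%) in the STAT5 comparison and 207 of 233 (88.8%) between controls. The median SD between probe sets of a gene was 0.23, 0.17 and 0.21, over 5555 genes.

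Alternatives were the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, no filter, a filter at percentile 75 (8.29), array median centring, intensity-dependent (loess, span 0.4) centring, and thresholds of 1.5-fold and 3-fold. Counting only genes 2-fold beyond all 3 other arrays was added after the data were seen, as were 9 gene families picked by symbol. The procedure was tested on simulated data with 200 changed genes among 12439. In the STAT3 comparison it called 50 of 50 genes changed 4-fold, 23 of 50 changed 2-fold and 8 of 50 changed 1.5-fold, with 166 of 12239 unchanged genes called (1.36%). In the STAT5 comparison it called 50, 23 and 4 of 50 and 8 unchanged genes (0.065%). Noise in the simulation was normal, had no shift and did not depend on expression level, with SDs of 0.41 and 0.29. These SDs were taken from the spread of the measured differences over genes in each pair, which also holds real effects. The shares of unchanged genes called describe the simulation only. They are not error rates of the real comparisons, which have no replicates. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.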

Results

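Gene expression was measured in mouse CD4+ T cells that had been activated for 72 h under conditions that favour Th17 differentiation, the T helper fate marked by IL-17 production. Naive cells (CD44-negative, CD62L-positive) were sorted from spleen and lymph nodes of C57BL/6J mice carrying the OT2 T cell receptor transgene. They were stimulated through CD3 and CD28 with IL-6 at 20 ng/ml and TGF-β at 2 ng/ml while IL-4 was blocked. The series asks what the transcription factors STAT3, activated by IL-6 and IL-21, and STAT5, activated by IL-2, contribute to expression in these cells. A floxed Stat3 allele or the floxed Stat5 locus was deleted by a Cre recombinase driven by the Cd4 promoter, and floxed mice without Cre gave the controls. STAT3-deficient cells and their controls were cultured with an antibody against IL-2 at 10 µg/ml, whereas STAT5-deficient cells and their controls received IL-2 at 100 IU/ml.

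There were 4 arrays, 1 per group: STAT3 wild type, STAT3-deficient, STAT5 wild type and STAT5-deficient. No group had a replicate, so no difference has a replicate check, no p-value is given, and the number of arrays limits the precision of every value. Levels are the deposited values, read here as log2, and a difference of 1 is a 2-fold change. A gene is called higher or lower where 2 arrays differed by at least 2-fold. Levels under 6.20, the median of all values, were treated as not distinguishable from background, so a fold change with one side under that level is uncertain in size. Of 18193 genes with a probe set of their own, 12439 had a level above 6.20 on at least 1 array and were compared. Array medians over all probe sets were 6.34 for STAT3 wild type, 6.10 for STAT3-deficient, 6.15 for STAT5 wild type and 6.21 for STAT5-deficient cells.

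The targeted genes were lower on the arrays whose titles name them as deficient. Stat3 stood at 12.87 on the STAT3 wild-type array and 9.93 on the STAT3-deficient array, a difference of -2.94 or 7.69-fold, against 12.33 and 12.80 (0.47) on the STAT5 wild-type and STAT5-deficient arrays. Of the other 3 probe sets for Stat3, 1 differed by -2.97 in that pair, and the remaining 2 by -0.22 and -0.41. Stat5a was at 10.92 in STAT5 wild-type cells and 5.91 in STAT5-deficient cells (-5.01, 32.3-fold). Stat5b was at 11.33 and 6.09 on the same arrays (-5.24, 37.7-fold), while its other probe set differed by -2.97. In this pair, 1 Stat3 probe set differed by -1.19. Without STAT3, Stat5a differed by -0.13 and Stat5b by -0.42. The labels do not give the deleted part of either gene, so the position of the probe sets relative to it is unknown, and a probe set outside it would check nothing.

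In STAT3-deficient cells Il17a and Il21, the cytokine genes analysed here from the Th17 list, were lower. Il17a, which encodes IL-17A, went from 14.12 in the control to 9.23 (-4.90, 29.8-fold), and Il21, a cytokine that acts back through STAT3, from 11.30 to 5.07 (-6.23). Il1r1, the IL-1 receptor through which IL-1 sustains Th17 cells, differed by -4.08, and Ahr, a ligand-activated transcription factor of these cells, by -2.71. Of the 14 measured genes of a Th17 list, 9 were lower and 0 higher. The list's median difference was -1.56, against -0.14 for random lists matched on expression, which placed it at percentile 0 of 10000 such lists. Rora, Maf, Batf, Hif1a and Irf4, transcription factors of the list, were at -1.85, -2.41, -1.52, -1.59 and -1.14. Ccr6, which encodes a homing receptor of Th17 cells, was at 0.50, within the 2-fold limit.

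Genes known to be induced by IL-6 through STAT3 were lower as a group, with 7 of 14 lower, 0 higher and a median of -1.16 (percentile 0). Socs3, the feedback inhibitor of IL-6 signalling, differed by -4.82 (28.2-fold), Il10, an anti-inflammatory cytokine, by -4.92, and Bcl3 by -2.46. Bcl6, the regulator of follicular helper cells, stood at -0.67, and Cish, a target of STAT5, at -0.18. Among all genes the largest decreases were in Serpinb1a, a protease inhibitor (-6.44), Il21, Gcnt2 (-6.13), Timp1, an inhibitor of metalloproteinases (-5.89), Tgfbi, an extracellular matrix protein (-5.55), Atp6v0d2, a subunit of the vacuolar proton pump (-5.23), and Olfm2 (-4.96), followed by Il10, Il17a and Socs3. Of these, all but Timp1, Il17a and Socs3 lay under the background level on the STAT3-deficient array, so their order and exact sizes are uncertain.

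Most measured genes of the Th1 list and some genes of other effector fates were higher in the STAT3-deficient cells. In the Th1 list, 9 of 13 measured genes were higher and 0 lower, with a median of 1.76 (percentile 100). Ifng, the Th1 cytokine gene, went from 3.84 to 8.56 (4.72), Tbx21, which encodes the Th1 regulator T-bet, was 3.69 higher, Il18r1 3.55 higher and Fasl, a death ligand, 3.62 higher. In the cytotoxic list, 4 of 8 measured genes were higher and 1 lower, and only the 4 higher genes lay above 0. The median of 1.34 (percentile 100) fell in the gap between Eomes (-0.05) and Gzmb, a granule protease (2.72). Nkg7, a protein of cytotoxic granules, differed by 6.12 and Klrk1 by 2.79, while Prf1 was at -0.99, Ctsw at -0.89 and Klrd1 at -1.27. Another 5 members, among them Gzma and Gzmk, lay under the background level on all 4 arrays. The Th2 list moved both ways, with 3 of 8 measured genes higher, 2 lower and a median of 0.28 (percentile 99.5). Il13 (3.33), Gata3, the Th2 regulator (3.22), and the chemokine receptor gene Ccr8 (2.78) were higher, and Il24 (-3.31) and Nfil3 (-1.42) lower. Il4 and Il5, cytokine genes of that list, lay under the background level on all 4 arrays. The largest increases overall were in Scin, an actin-severing protein (6.13), Nkg7, Trat1, an adaptor of the T cell receptor (5.98), Lad1 (5.86), Car2, a carbonic anhydrase (5.66), Mndal (5.25), Idi2 (5.20), the chemokine gene Ccl1 (5.06), Ncf1, a subunit of the phagocyte oxidase (4.99), and Ifng. The controls of all but Lad1, Car2 and Mndal lay under the background level, with the same uncertainty.

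The regulatory T cell list had 5 of 15 genes higher and 1 lower without STAT3, with a median of 0.26 (percentile 99.96). Ikzf2, which encodes Helios, was 3.74 higher, Nrp1 2.59, Ebi3 1.97 and Tnfrsf18 1.24 higher. Foxp3, the regulator that defines these cells, lay under the background level on both arrays of the pair, at 3.94 and 3.32 (-0.63), and Il2ra differed by -0.89, or by -1.13 with its probe sets averaged. In the interferon list, 9 of 24 genes were higher and 1 lower (median 0.27, percentile 100), led by Xaf1 (4.12), Iigp1 (3.42), Isg20 (2.85) and Ifih1 (2.02). The follicular helper list had 4 higher, such as Sh2d1a (1.79), and 4 lower, including Pou2af1 (-3.72) and Cxcr5 (-1.95). Its median of 0.10 (percentile 98.9) lost its place outside the random lists under a stricter expression filter, at -0.10.

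Early response genes of T cell receptor signalling had a median of 0.39 (percentile 100), with Nr4a3 (3.09), Tnf (1.26) and Egr2 (1.07) among the 3 higher genes and Jun (-1.21) the 1 lower. Averaged over their probe sets, Nr4a3 and Egr2 stood at 0.92 and 0.89. Of 26 cell cycle genes, 21 lay above 0, with a median of 0.30 (percentile 100), and 0 passed 2-fold. Ccne2 was the farthest member and lay on the other side, at -0.998. As deposited, all 14 glycolysis genes lay below 0, with a median of -0.44 (percentile 0.4), whereas Pgk1 (0.09) and Ldha (0.02) lay above 0 with arrays centred, and 1 passed 2-fold, the lactate transporter gene Slc16a3 (-1.05). Cholesterol synthesis genes had a median of 0.14 (percentile 99.5) with 0 past 2-fold, and Mvd, at -0.59, lay farthest out. Genes of the unfolded protein and amino acid response had a median of 0.20 (percentile 99.7). That fell to -0.03 (percentile 90.5) with probe sets averaged, where Sesn2 went from 1.002 to 0.63.

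Genes that IL-2 and STAT5 are known to induce did not stand apart without STAT3 (median -0.18, percentile 42.0), with Gzmb (2.72), Socs2 (1.86) and Lta (1.19) higher and Il4ra (-2.57) and Osm (-1.36) lower. For Socs2 the mean of its probe sets was 0.89. Of 5 measured genes that IL-2 and STAT5 are known to repress, 1 was lower (Il7r, -1.16) and 1 higher (Ccr7, 1.04). Their median of -0.67 lay at percentile 1.91 and, with probe sets averaged, at -0.31 and percentile 25.7. Naive and central memory genes moved both ways (median -0.10, percentile 66.2), with Klf2 (2.03) and Id3 (1.76) higher and Satb1 (-2.76) lower. TGF-β response genes (median -0.24, percentile 27.8) moved both ways, with Smad3 (-2.40), Id2 (-1.60) and Ldlrad4 (-1.49) lower and Id3 and Id1 (1.28) higher. Heat shock genes (median -0.17, percentile 46.4) included Hspa1b (-2.07) and Hspa1a (-1.73). Apoptosis regulators had a median of 0.07 (percentile 96.9, or 98.2 with probe sets averaged), with Fasl higher and Pmaip1 (-1.89) lower. The CD4 T cell identity genes had a median of -0.22 (percentile 22.9) and 0 of 10 past 2-fold, with Cd28 farthest at -0.95, or at -1.03 with its probe sets averaged.

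In all, 354 genes were higher and 900 lower in STAT3-deficient cells, 10.1% of the genes compared, and 47 and 63 passed 8-fold. The median gene differed by -0.20, so the split depends on the scaling: 71.8% of called genes were lower as deposited, 54.0% with each array centred on its median (512 higher, 601 lower) and 53.8% after intensity-dependent centring (498 higher, 581 lower). With array centring, Irf4, Il7r, Jun and Slc16a3 fell short of 2-fold, at -0.92, -0.94, -0.99 and -0.83, which left 8 lower genes in the Th17 list. Other list members, such as Bach2 (-0.89) and Ctla4 (-0.92), lost their calls too. Some calls were gained: the apoptosis list went from 1 to 4 higher genes, with Bid at 1.19 and Bcl2l11 at 1.15.

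**Figure D1:**
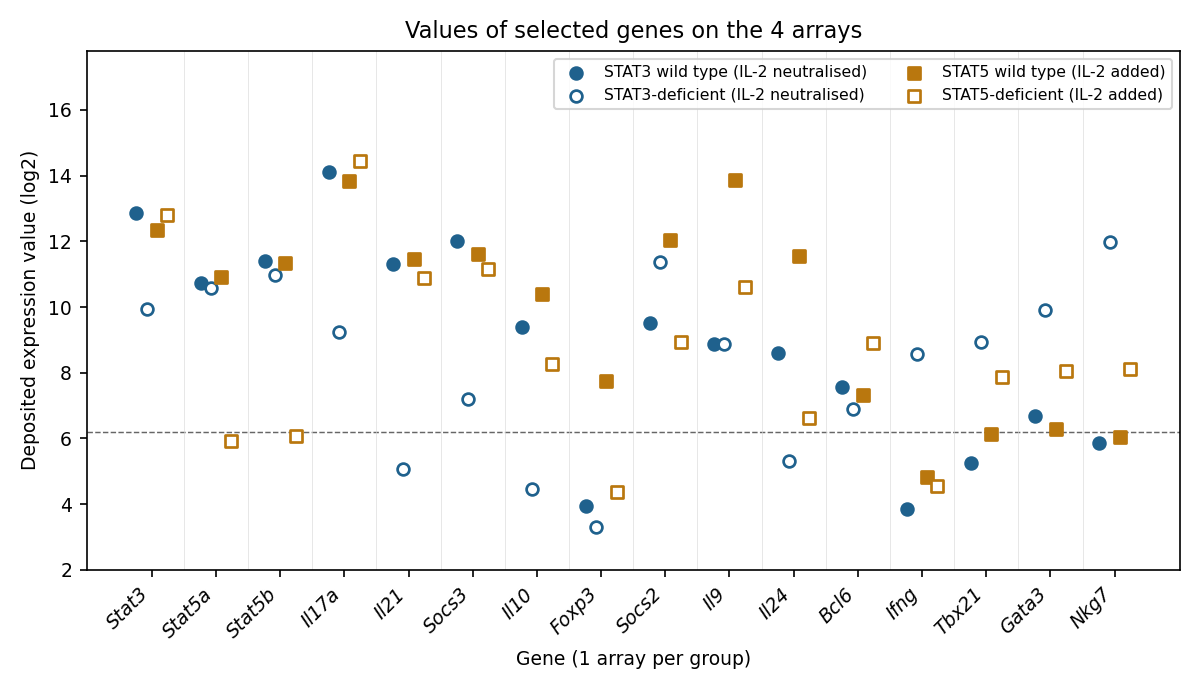
Deposited log2 values of 16 genes on the 4 arrays, with genes along the horizontal axis. Circles are the STAT3 pair and squares the STAT5 pair, filled for wild type and open for deficient cells, and the dashed line is the background level of 6.20. Il17a lies at 9.23 in STAT3-deficient cells and between 13.85 and 14.44 on the other arrays, and Foxp3 passes the line in STAT5 wild-type cells alone.

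In STAT5-deficient cells, cultured with IL-2, Foxp3 was lower and Il17a close to its control. Foxp3 went from 7.73 to 4.36 (-3.37, 10.3-fold), and 4 of 15 genes of the regulatory T cell list were lower and 0 higher, with a median of -0.30 (percentile 0.035). Izumo1r, the folate receptor 4 of regulatory T cells, was at -2.33, Ikzf4, which encodes the Foxp3 partner Eos, at -1.25 and Entpd1, which encodes CD39, at -1.21, while Il2ra was at -0.30. Il17a stood at 13.85 in the control and 14.44 without STAT5, a difference of 0.59 that did not reach 2-fold. Il21 stood at -0.60, or at -1.03 with its probe sets averaged, past 2-fold. In the Th17 list 2 of 14 genes were higher, Il1r1 (1.75) and Batf (1.001), and 0 lower. The list's median of 0.38 lay at percentile 100, but averaging probe sets brought it to 0.13 (percentile 84.3) and Il1r1 to 0.92, and Batf stood at 0.96 with arrays centred.

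Genes known to be induced by IL-2 through STAT5 were lower as a group, with 4 of 15 lower, 1 higher and a median of -0.53 (percentile 0). Socs2, a feedback inhibitor of cytokine signalling, differed by -3.12 (8.68-fold), Lta, the lymphotoxin gene, by -2.52, Bcl2, a survival factor, by -1.60 and Pim2, a kinase, by -1.02. Cish, another classical target, was at -0.35, and Gzmb was higher by 1.53. Of the 5 genes that IL-2 and STAT5 are known to repress, Bcl6 (1.59) and Il7r, the IL-7 receptor (1.21), were higher and Ccr7 (-1.03) lower, with a median of 0.26 (percentile 94.1). The IL-6 and STAT3 list had 3 genes higher, Fos (1.73), Bcl6 and Batf, and 1 lower, Il10 (-2.12), while Socs3 stood at -0.45. Its median of -0.24 (percentile 0.02) came to -0.03 (percentile 8.81) with probe sets averaged.

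The largest decrease after Stat5b and Stat5a was in Il24, a cytokine of the IL-10 family. It went from 11.55 to 6.63 (-4.92, 30.3-fold). Il9, the cytokine of Th9 cells, went from 13.88 to 10.61 (-3.27), Gata3 was 1.75 higher, and the median of the Th2 list was -0.34 (percentile 0.3). Procr, the protein C receptor (-3.56), F3, tissue factor (-3.31), Enah (-3.24) and C1s1, a complement protease (-3.18), completed the largest decreases with Foxp3 and Socs2. The largest increases were in Tgfbi (3.83, 14.3-fold), Mndal (3.63), Vegfc, a lymphatic growth factor (3.42), P2ry6 (3.22), Casp1, the inflammasome protease (3.12), Slc12a1 (2.99), Dhrs3 (2.83), Serpinb9, an inhibitor of granzyme B (2.70), Cd24a (2.69) and Dclk1 (2.59). On the lower side of these differences all but Il24, Procr, Il9, Socs2, Tgfbi, Cd24a and Dclk1 lay under the background level, so their exact sizes are uncertain.

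The Th1 list had 3 of 13 genes higher without STAT5 and 0 lower: Tbx21 (1.74), Il18rap (1.41) and Cxcr3 (1.19). Its median of 0.43 (percentile 99.96) came to 0.19 (percentile 89.6) with probe sets averaged, and Ifng stayed under the background level at 4.84 and 4.56. In the follicular helper list, 5 of 14 genes were higher and 0 lower, among them Tox2 (2.12), Pou2af1 (1.64), Bcl6 and Pdcd1, which encodes PD-1 (1.32), although the median of 0.12 did not stand apart (percentile 75.8). In the cytotoxic list (median 0.09, percentile 54.2), Nkg7 was at 2.07 and Klrd1 at -1.56. Naive and central memory genes had a median of 0.47 (percentile 100) with Il7r higher and Ccr7 lower. Il2, the gene of the cytokine upstream of STAT5, was 2.33 higher, and Fos and Nr4a2 (1.69) were the other 2 higher genes of the T cell receptor list (median -0.02, percentile 16.1).

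Glycolysis genes had a median of -0.16 (percentile 0.05), with the glucose transporter gene Slc2a3 at -1.65, and cell cycle genes a median of 0.26 (percentile 100), with 0 past 2-fold and Plk1 farthest at 0.45. The amino acid response list had a median of -0.16 (percentile 1.22), with the stress-induced factor gene Atf3 at -2.19. CD4 T cell identity genes had a median of 0.25 (percentile 99.4) and 0 past 2-fold, with Cd2 farthest at -0.72. Interferon genes did not stand apart (median -0.04, percentile 9.18, with Gbp3 at 1.49 and Iigp1 at -1.33), nor did apoptosis (0.03, percentile 35.7), cholesterol synthesis (-0.06, percentile 3.79, with Insig1 farthest at 0.34) or heat shock (0.08, percentile 61.4, with Hspa1a at 1.51). The TGF-β list (0.17, percentile 89.6, with Id1 at -1.80 and Tgif1 at 1.07) changed with the processing, to 0.43 (percentile 99.99) with probe sets averaged and 0.28 (percentile 99.4) under the stricter filter. In all, 231 genes were higher and 217 lower, 3.60% of the genes compared, and 6 and 12 passed 8-fold. The lower genes made up 48.4% of these as deposited and 57.4% after intensity-dependent centring.

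**Figure D2:**
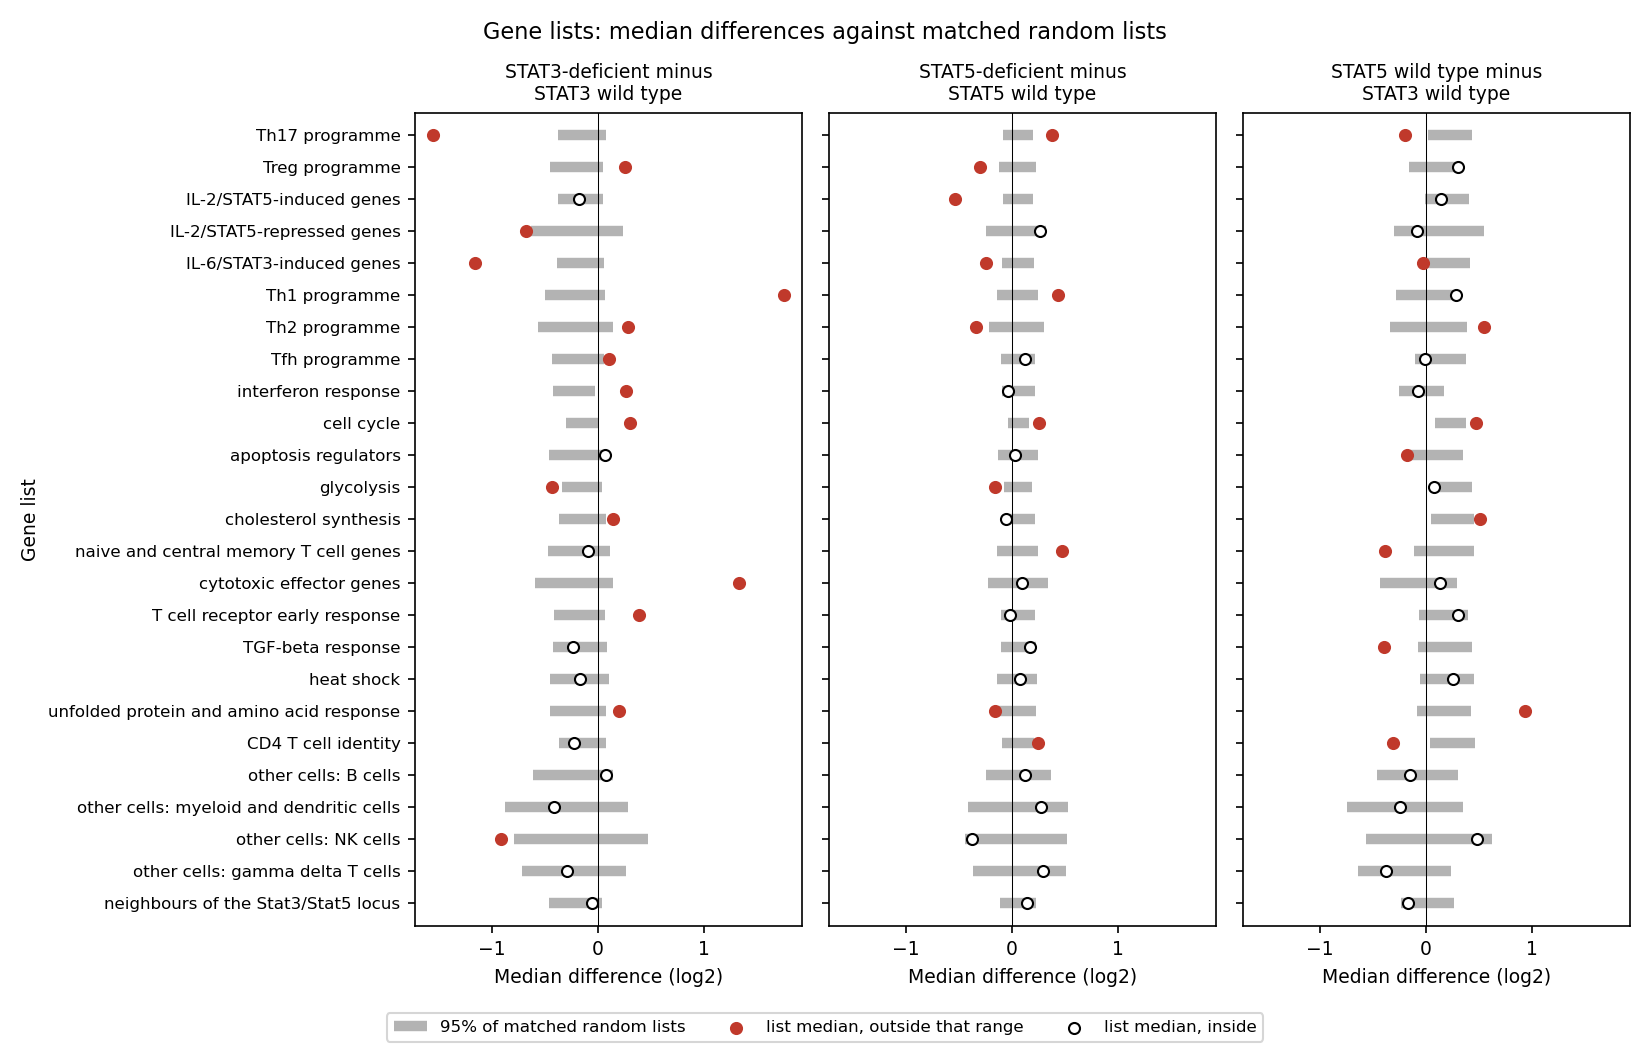
Median log2 difference of each gene list in the STAT3-deficient minus wild-type comparison, the STAT5-deficient minus wild-type comparison and the comparison of the wild-type arrays. Grey bars span the middle 95% of 10000 random lists matched on expression, and red points are medians outside that range. The Th17 list lies at -1.56 without STAT3 and 0.38 without STAT5, and the Th1 list at 1.76 and 0.43. With probe sets averaged, their medians without STAT5 were 0.13 and 0.19, inside the random range.

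The effects of the 2 deletions share no array, so they were set against each other gene by gene. Tgfbi had the widest gap, at -5.55 without STAT3 and 3.83 without STAT5. Atp6v0d2 (-5.23 and 1.31), Cdh17, a cadherin (-4.39 and 1.74), Olfm2 (-4.96 and 1.13) and Tmem176a (-4.59 and 1.33) followed in that direction. In the other direction, Ncf1 was at 4.99 without STAT3 and -2.53 without STAT5, Acsl6, an acyl-CoA synthetase, at 4.71 and -2.23, Csf2, which encodes GM-CSF, at 4.17 and -2.52, Socs2 at 1.86 and -3.12, and Tead1 at 2.38 and -2.51. Averaged over its probe sets, Socs2 stood at 0.89 without STAT3, which ends its call as an opposed gene. Il10 and Il24 were lower without either factor, and Nkg7, Tbx21, Gata3, Gzmb and Mndal were higher without either.

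Counted over all genes, 69 were lower without STAT3 and higher without STAT5, against 16.7 for lists of these sizes drawn independently, and 22 were higher and then lower, against 6.18. The imbalance between these directions depends on the scaling, with 60 and 27 genes after array centring and 52 and 32 after intensity-dependent centring. Genes moving the same way were also more numerous than in independent lists, with 47 higher in both, against 6.57, and 68 lower in both, against 15.7. Independent lists give every gene the same likelihood of passing 2-fold, without matching on expression or variability. Every combination of directions exceeded them, so the excess alone does not show shared or opposed regulation. Across the 12439 genes the effects had a Pearson r of 0.075 and a Spearman rho of 0.11, and genes are not independent replicates. The pairs also differ in IL-2 and in floxed line, so a gene's effects were measured in different settings, and their difference was not tested.

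**Figure D3:**
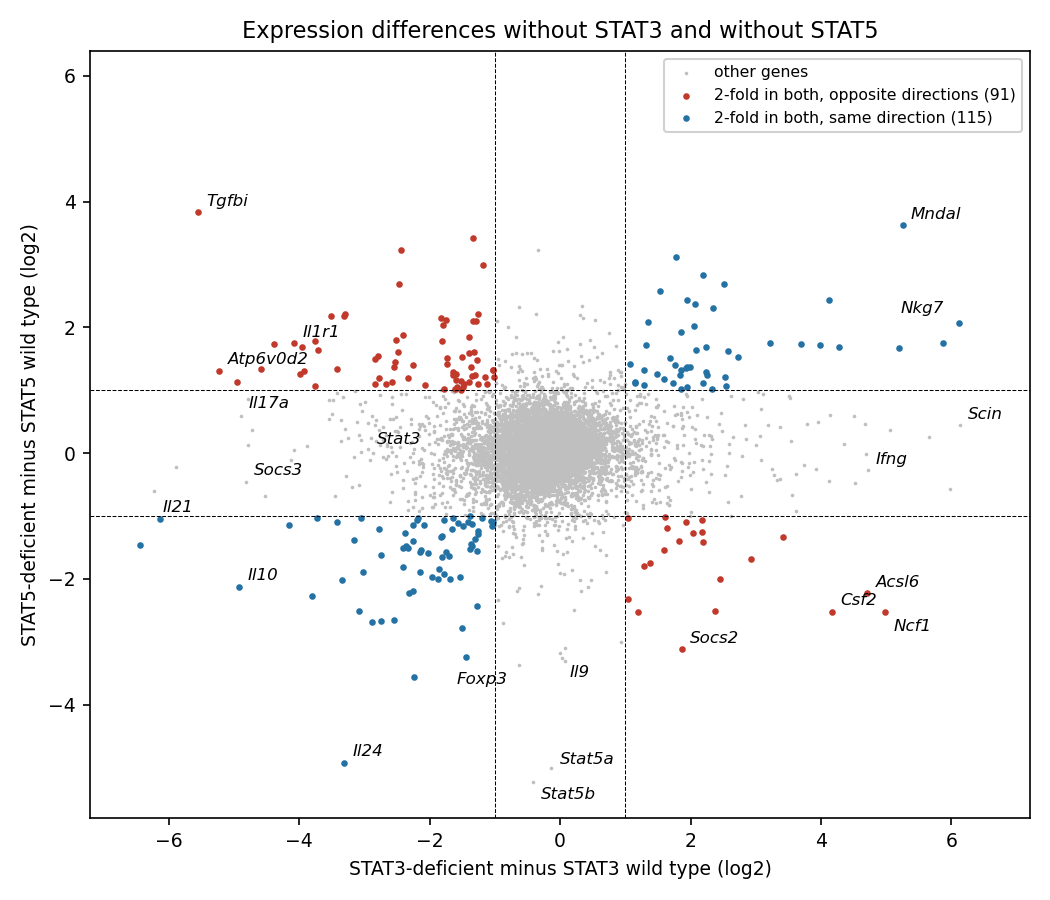
Each point is one of 12439 genes, with the log2 difference between STAT3-deficient and STAT3 wild-type cells on the horizontal axis and that between STAT5-deficient and STAT5 wild-type cells on the vertical axis. Dashed lines mark 2-fold, red points are the 69 and 22 genes past it in opposite directions, and blue points the 47 and 68 past it in the same direction. Tgfbi lies at -5.55 and 3.83.

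The wild-type arrays differ in IL-2, added or neutralised, and in floxed line, and these cannot be told apart. The STAT5 control array enters both this difference and the STAT5 effect. A value high on that array alone would raise a gene here and lower it without STAT5. For Il9, Foxp3, Lta and Socs2 these differences are therefore not independent of each other, and Foxp3 passed the background level on that array alone. The STAT3 control array in turn enters both the difference between controls and the STAT3 effect. A value high on it alone would lower a gene in both. The differences of Atp6v0d2 (-5.23 without STAT3) and of the Th17 list are therefore not independent of each other either. Il9 was the gene farthest above the STAT3 control in the STAT5 control, at 13.88 against 8.87 (5.01, 32.3-fold), and Foxp3 was at 7.73 against 3.94 (3.79). Cd36, a fatty acid transporter (3.78), Zfp979 (4.08) and the immunoglobulin segment Igkv8-30 (3.73) were also higher. Lta (2.77) and Socs2 (2.54) were among 3 of 15 higher genes in the IL-2 and STAT5 induced list, although its median of 0.14 did not stand apart (percentile 27.8). Atp6v0d2 (-3.73), Atp6v0e2, another proton pump subunit (-3.60), Rasgrp3 (-3.58), the growth factor gene Csf1 (-3.35) and Gdpd3 (-3.32) were lower. Il17a differed by -0.27, Il21 by 0.17, Il2ra by 0.14, Socs3 by -0.40, Cish by 0.35, Bcl6 by -0.25, Stat3 by -0.54, Stat5a by 0.19 and Stat5b by -0.06.

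Between the controls, the amino acid response list had the largest median of the lists fixed beforehand, with 5 of 11 genes higher, 0 lower and a median of 0.94 (percentile 99.99). Atf3 (2.86), Chac1 (2.24), Asns, asparagine synthetase (2.11), Trib3 (1.95) and Sesn2 (1.86) were those higher genes. The Th2 list (0.55, percentile 99.7), cell cycle (0.47, percentile 99.9) and cholesterol synthesis (0.51, percentile 99.2) also lay above the random lists. The Th2 median was 0.24 (percentile 94.2) without the expression filter, and the cholesterol one 0.36 (percentile 97.0) with probe sets averaged. Below them lay Th17 (-0.20, percentile 0.02), CD4 T cell identity (-0.32, percentile 0), TGF-β response (-0.40, percentile 0.01), naive and central memory (-0.39, percentile 0.04), IL-6 and STAT3 induced (-0.03, percentile 1.81) and apoptosis genes (-0.18, percentile 1.58). Apoptosis genes reached percentile 3.12 without probe sets that can match several transcripts.

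The other lists of T cell programmes and pathways lay inside the range of random lists for this difference, and some of them left it under alternatives. Th1 genes (0.28, percentile 96.3) came to 0.55 (percentile 99.0) under the stricter filter and 0.37 (percentile 99.2) with intensity-dependent centring. Follicular helper genes (-0.01, percentile 10.9) came to -0.15 (percentile 1.18) with probe sets averaged and -0.12 (percentile 1.61) under the stricter filter. T cell receptor genes (0.30, percentile 87.4) reached percentile 99.0 with intensity-dependent centring. Regulatory T cell genes, with 5 of 15 higher and 1 lower (0.30, percentile 95.3), came to 0.36 (percentile 98.6) with probe sets averaged and 0.49 (percentile 100) with intensity-dependent centring. The rest stayed inside: interferon (-0.08, percentile 36.5), cytotoxic (0.13, percentile 86.5), glycolysis (0.08, percentile 3.72), heat shock (0.26, percentile 67.1) and IL-2 and STAT5 repressed genes (-0.09, percentile 13.7). In all, 292 genes were higher and 367 lower, 5.30% of the genes compared, and 9 and 8 passed 8-fold. The lower genes made up 55.7% as deposited and 50.3% after intensity-dependent centring.

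Markers of other cells were followed beside these comparisons. For B cells, 7 of 12 markers passed the filter, with a median of 0.07 without STAT3 (percentile 94.5), where Cd74, the invariant chain, was 3.06 higher, and 0.12 without STAT5 (percentile 60.2), where H2-Aa was at 0.66. Without STAT3 the B cell list came to 0.22 without the filter, 0.48 under the stricter filter, 0.37 with arrays centred and 0.46 with intensity-dependent centring, each outside the random range, and without STAT5 to -0.48 (percentile 0.68) under the stricter filter. Myeloid and dendritic markers had medians of -0.41 (percentile 34.5) and 0.28 (percentile 81.6), with S100a9 farthest at -0.48 and 0.93. The 3 measured NK cell markers had medians of -0.91 (percentile 1.15) and -0.38 (percentile 3.69), with Klrd1 at -1.27 and -1.56. Without the filter the NK list came to -0.28 (percentile 33.3) without STAT3 and -0.49 (percentile 0.17) without STAT5, so neither call was stable. With intensity-dependent centring the former lay at percentile 4.54, and with probe sets averaged the latter at percentile 2.07. Among CD8 T cell markers, Cd8a differed by -0.70 and Cd8b1 by -0.15 without STAT3, and by 0.02 and 0.11 without STAT5. Gamma delta T cell markers had medians of -0.29 (percentile 44.7) and 0.29 (percentile 82.5), with Blk farthest at -0.51 and 0.66. The 2 erythroid markers measured stayed under the background level on all 4 arrays. In the difference between controls, the B cell, myeloid, NK and gamma delta lists had medians of -0.15, -0.25, 0.48 and -0.38, at percentiles 35.8, 49.4, 94.6 and 22.6, and NK markers reached percentile 99.4 without the filter. Outside the B cell list, the immunoglobulin segment Igkv8-30 was 3.73 higher there, at 10.42 against 6.69, by a probe set that can match several transcripts.

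Xist, which is expressed from the inactive X chromosome, lay between 13.21 and 13.42 on all 4 arrays, and the Y-linked genes measured lay under the background level on all 4. Genes next to the Stat3 and Stat5 locus had a median of -0.06 without STAT3 (percentile 89.0), 0.14 without STAT5 (percentile 81.6, or 98.4 with arrays centred) and -0.17 between controls (percentile 6.68). Among them, Cavin1 was at 2.04 without STAT3 and -1.26 without STAT5, and Atp6v0a1 at -1.56 without STAT3. With probe sets averaged, Cavin1 came to 0.46 and -0.38. As a sign of RNA quality, 3′ minus 5′ control probe sets differed by 0.13 to 0.23 for Actb and by -0.08 to 0.04 for Gapdh.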

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

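The tests of explanations in this part were chosen after the results were seen, whereas the counts of genes and the B cell list were planned.

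Genes whose expression moved in opposite directions without STAT3 and without STAT5 were flagged. The difference between the effects was not tested, since each rests on 1 array per group. Genes moving the same way were also in excess over independent lists. In both, 47 were higher, against 6.57, and 68 lower, against 15.7, so opposite movement was not the only pattern. Independent lists give every gene the same likelihood of passing 2-fold, so an excess over them alone does not show shared or opposed regulation. There were 69 genes lower without STAT3 and higher without STAT5, and 22 the other way round, or 60 and 27 with arrays centred and 52 and 32 with intensity-dependent centring. The gap, as STAT5 effect minus STAT3 effect, was widest for Tgfbi (9.39), Atp6v0d2 (6.54), Cdh17 (6.13), Olfm2 (6.09) and Tmem176a (5.92) on one side. On the other side it was widest for Ncf1 (-7.52), Acsl6 (-6.94), Csf2 (-6.69), Socs2 (-4.98) and Tead1 (-4.89). With probe sets averaged the STAT3 effect of Socs2 was 0.89, short of 2-fold.

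Probe sets that name no gene, controls aside, were not part of any comparison, and some of them differed by 2-fold. The 932 probe sets naming several genes were also left out and are not in the counts that follow. Of 3123 probe sets past the filter that name no gene, 300 differed without STAT3 (49 higher, 251 lower) and 94 without STAT5 (57 higher, 37 lower). Between the controls 292 differed (59 higher, 233 lower). The STAT3 control array is subtracted in the first and the last of these comparisons, so their excess of lower probe sets is not independent.

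Effector genes such as Nkg7, Ifng, Tbx21, Il13 and Gata3 were higher on the STAT3-deficient array, and cells of another type in the culture are a candidate explanation. Such cells would bring their own abundant transcripts. The NK cell genes Tyrobp, Fcer1g, Ncr1 and Klra8 had a median difference of -0.28 (SD 0.20), Cd8a and Cd8b1 of CD8 T cells -0.43 (SD 0.39), and H2-Aa, H2-Ab1, Cd79a, Ms4a1 and Itgax of B and dendritic cells 0.072 (SD 0.43), each below 1 by more than the SD, so none of these marker sets rose 2-fold with the effector genes. Most of these markers lie under the background level. The B cell list, led by Cd74, passed the random lists under 4 alternatives, at percentiles 97.9 to 99.6 and medians of 0.22 to 0.48. A small share of B cells is therefore not excluded by these values. The cultures began from sorted naive CD4+ T cells (CD44-negative, CD62L-positive), a sort meant to leave out such cells, but its purity was not available here. Loss of STAT3 itself remains a hypothesis, and a difference between single cultures stays open without replicates.

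More genes were lower than higher on the STAT3-deficient array, 900 against 354, and array scaling may account for part of that. The 18 spike-in control probe sets, added at fixed amounts, differed by a median of -0.10 (SD 0.097) in this pair, between 0 and the median gene at -0.20. In the STAT5 pair they differed by -0.12 (SD 0.096) while the median gene stood at 0.06, so the controls do not track the genes closely enough to decide. Scaling and a true excess of lower genes therefore cannot be told apart for the split, and no biological explanation for it was tested.

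Genes for the enzymes that load amino acids onto tRNA in the cytosol were higher in STAT5 wild-type than in STAT3 wild-type cells, with a median of 1.09 over 15 genes. IL-2 acting through STAT5 would predict a loss without STAT5, but their median STAT5 effect was 0.058 (SD 0.16), with no drop toward the STAT3 control. On the STAT5-deficient array they were also above the STAT3-deficient array, by a median of 1.10 (SD 0.30), so the rise is shared by the pair. A culture or array batch of the pair cannot be told apart from IL-2 acting through another route or from the floxed line, because each pair has a single IL-2 condition and line.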

How the results depend on the processing

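Alternatives were planned except counting genes 2-fold beyond all 3 other arrays, which was chosen after seeing the data. No result past its limit reversed. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array. Of 176 named gene values, 162 kept their side of the 2-fold limit under every alternative run, and of 75 list medians 54 kept their side of the random range. Averaging probe sets ended 3 list results without STAT5: Th17 at 0.13, IL-6 and STAT3 induced at -0.027 and Th1 at 0.19, and the cause was not tested. The counts of genes depended on threshold and filter. Without a filter, 383 genes were higher without STAT5 and 631 lower between controls, and rho of the effects was 0.052. With the filter at percentile 75, fewer genes were tested, and 223 were higher and 551 lower without STAT3, 126 and 128 without STAT5, 151 lower between controls and 41 lower then higher, with rho at 0.16. Intensity-dependent centring left 581 lower without STAT3. At 1.5-fold, 704 were higher and 2389 lower without STAT3, 800 and 644 without STAT5, 1344 and 1240 between controls, 246 and 78 opposite, and 132 and 260 shared higher and lower. At 3-fold these were 179 and 343, 73 and 70, 82 and 95, 18 and 7, and 20 and 23. Beyond all 3 other arrays, 187 genes were higher and 387 lower without STAT3, and 46 and 35 without STAT5. Signal near background limits folds with a side under 6.20.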

Other observations

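The gene families in this part were picked by symbol after the data were seen, and their values are described without a test. For ligands of the TNF superfamily only genes with a Tnfsf symbol were taken, which leaves out Lta, Tnf and Fasl. Without STAT3, 3 of these 7 ligands were higher and 0 lower. All 7 lay above 0, with a median of 0.97 (percentile 99.99 of matched random lists). Tnfsf11, the osteoclast factor RANKL (3.98), Tnfsf10, the death ligand TRAIL (2.62), and Tnfsf8 (2.30) passed 2-fold. With each array centred on its median 6 of the 7 passed, since Tnfsf13b, Tnfsf4 and Tnfsf9 then stood at 1.08, 1.19 and 1.18. Genes of the TNF receptor superfamily leaned the other way, with 6 of 16 lower and 3 higher and a median of -0.70 (percentile 0.01). Among them were Tnfrsf23 (-2.51), Tnfrsf21 (-1.82) and Tnfrsf13c (1.94). These were taken as a family, and ligands were not matched to their own receptors. CC chemokines had 5 of 12 higher and 0 lower (median 0.34, percentile 99.9), with Ccl1 (5.06), Ccl22 (3.93), Ccl3 (3.50) and Ccl4 (2.43), which attract T cells and monocytes. Chemokine receptors moved both ways, with Cxcr6 (-3.75) and Cxcr4 (-2.82) lower and Ccr8 (2.78) higher (median 0.10, percentile 97.2). The Tnfsf genes and CC chemokines also lay above the random lists without STAT5. There the 7 Tnfsf genes had a median of 0.57 (percentile 99.89), with 2 higher (1 with arrays centred) and 0 lower. That median is the value of Tnfsf13b, which lay under the background level on both arrays of the pair (5.21 and 5.79). The ligand genes left out went the other way there, with Lta at -2.52, Tnf at -0.59 and Fasl at -0.33. The CC chemokines had a median of 0.42 (percentile 99.75), with 1 higher and 0 lower. The higher gene, Ccl8, lay under the background level on both arrays of the pair (4.70 and 5.98), as did Ccl1 and Ccl9. Their differences there are not distinguishable from background.

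Without STAT5, Cxcr6 was 1.79 higher, and the 10 chemokine receptors had a median of 0.47 (percentile 99.99), with 2 higher and 1 lower. Between the controls they had a median of -0.61 (percentile 0), with 0 higher and 3 lower. Guanylate-binding proteins, which are induced by interferon, had a median of -2.26 over 5 genes (percentile 0) in the STAT5 control against the STAT3 control, with values of -2.80 for Gbp2 and -2.58 for Gbp3. Without STAT5 their median was 0.91 (percentile 99.98), with Gbp6 (2.31) and Gbp3 (1.49) past 2-fold. Gbp8 lay under the background level on both arrays of each of these differences, and Gbp7 on both arrays of the STAT5 pair, so their values there are not distinguishable from background. For both families the STAT5 control array enters the STAT5 effect and the difference between controls, which by itself turns them in opposite directions. In the STAT3 pair, which does not hold that array, the guanylate-binding proteins had a median of 0.91 (percentile 99.91). Gbp6 (2.34) and Gbp7 (1.46) were higher there and Gbp2 (-1.79) lower.

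The cytosolic tRNA synthetases had 9 of 15 genes past 2-fold between controls, led by Cars (1.90), Gars (1.31) and Iars (1.28), and the 15 mitochondrial synthetases had a median of 0.15 (percentile 73.0) with 0 past 2-fold. Proteasome subunits had a median of 0.46 over 37 genes between controls (percentile 99.95) with 0 past 2-fold, and 44 ribosomal protein genes one of 0.08 (percentile 0.69). Mndal, higher without either factor, lay at 6.21, 11.46, 3.77 and 7.40 on the STAT3 wild-type, STAT3-deficient, STAT5 wild-type and STAT5-deficient arrays. In the same order, Xaf1 lay at 6.32, 10.44, 4.14 and 3.70, and Zfp979 at 2.90, 2.99, 6.98 and 6.88.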
